A study of Drosophila melanogaster with 2 samples.

How the data were processed

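The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from whole Drosophila melanogaster embryos of mixed sex, collected 0 to 24 h after laying. Per the labels, the flies carried an eGFP exon in an intron of p53, so that the endogenous gene made a p53-eGFP fusion protein, and chromatin was sonicated to 200 to 800 bp. The labels name the antibody target as p53 in one field, and describe the precipitation as done with an anti-GFP antibody in another. The 2 samples are biological replicates numbered 2 and 3, and form 1 group.

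Per the deposited provenance lists, each replicate has its own peak list, a pooled list was made from both replicates, and a final list was selected by the irreproducible discovery rate (IDR), a measure built on how peaks rank in both replicates. Each list exists in the dm3 and dm6 builds. Both replicates were set against the same control library, which was not used here. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The authors' signal value per peak is a peak strength whose scaling is not given in the sources used here. The deposited −log10 q-value per peak stands beside it. No IDR value per peak was used, because the score column of the final list holds 0 throughout. Signal values are the authors' own, and were used only to rank, filter and describe peaks within a list. The number of reads behind a peak is unknown, so intervals on shares of peaks cover counting error only.

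The per-replicate and pooled lists hold peaks together with background regions meant as IDR input. In dm6 these lists hold 30000 regions for replicate 2, 30000 for replicate 3 and 26752 for the pool. A deposited q of 0.01 or less was held by 1847 regions of replicate 2, 4186 of replicate 3 and 3355 of the pool, so replicate 3 gave more called regions than replicate 2. All 2290 final peaks in dm6 were the 2290 strongest pooled regions by signal value, and the same held for the 2309 final peaks in dm3. The final list is called the IDR list here. The 24040 pooled regions that overlap no IDR peak are called candidate peaks, and served as the background for comparison. Only 3355 of the 26752 pooled regions, all 2290 IDR peaks among them, had a q of 0.01 or less. Most candidate peaks thus did not reach that q. Comparisons with them set IDR peaks mostly against regions that were not called at it.

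Coordinates are dm6 and 1-based. The reference genome was Release 6, with Ensembl gene models of the same assembly, and every dm6 peak ended within the reference chromosome lengths. The dm3 lists were used for counts and for replicate overlap, with no conversion between builds. A summit was assigned, in this order, to promoter (within 500 bp of a protein-coding transcription start site, TSS), 5′ UTR, coding exon, 3′ UTR, intron, non-coding gene or intergenic sequence. A gene counted as having a peak when an IDR summit lay within 1 kb of any of its TSSs. Sequence words were searched on both strands within 100 bp of the summit. The p53 half-site was RRRCWWGYYY, where R is A or G, Y is C or T and W is A or T. A full p53 site was a pair of half-sites with a spacer of 0 or 1 bp and at most 3 mismatches in 20 positions.

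Shares of IDR and candidate peaks were compared by two-sided Fisher's exact tests. Words at the summit were compared with a window of the same size 1 kb away, outside that peak, on a side drawn at random. The test was a two-sided exact binomial test on the peaks with the word in 1 window only. The overlap of the replicates' top peaks was compared with 1000 random placements of replicate 3's peaks on the same chromosomes, in a one-sided permutation test. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, and tRNA genes with all other genes. P-values were adjusted by the Benjamini-Hochberg method over the 7 annotation classes, 6 chromosome arms, 11 words or 13 gene lists, and the threshold was 0.05. Intervals on shares are 95% Wilson intervals. Neighbouring genes share peaks, so p-values over genes are approximate, and circular shifts of the peak labels along each arm were run as an alternative.

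These tests, the lists and the words were fixed before the data were examined. The named genes are those nearest to the 25 IDR peaks with the highest signal value, p53, every member of the list of p53 radiation-response targets, and up to 4 members of each other list with the strongest peak within 1 kb of a TSS. In the germline list, 26 of 27 members were matched to the annotation, and nos was left out because its older symbol matched more than 1 gene. The alternatives were each replicate's own list without the other, the upper part of the IDR list by signal value, other windows, other backgrounds, other overlap rules and the dm3 lists. Leaving out a replicate meant taking the 2290 strongest regions of the other replicate's list.

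The statistics were tested on simulated data. For shares of 2000 simulated peaks against candidates, a share of 60% came back as 59.95%, and 5% of draws with no difference had p under 0.05. For words at 2000 simulated summits, a share of 23.6% came back as 23.55%. For the overlap of 2000 simulated peaks per replicate, 69.1% shared came back as 67.8%. For gene lists over 14000 simulated genes, the planted list was called in 100% of draws and null lists in 0.167%. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.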

Results

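The series profiled where a p53-eGFP fusion protein sits on the genome of Drosophila embryos. p53 is a transcription factor that responds to DNA damage, and the fusion was made from the endogenous locus. Chromatin from whole embryos aged 0 to 24 h was immunoprecipitated in 2 biological replicates, numbered 2 and 3. There is 1 group and no second condition, so the comparisons are between replicates, between final and candidate peaks, between summits and their flanks, and between gene lists. The IDR list in dm6 held 2290 peaks, with a median width of 396 bp and signal values from 75.8 to 1970. The dm3 list held 2309 peaks.

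The first question was how far the replicates marked the same regions. The strongest region in both replicates' lists was the same, a peak 361 bp from a TSS of Xrp1, which encodes a bZIP transcription factor. All 25 of the strongest IDR peaks ranked among the top 37 regions of replicate 2 and the top 25 of replicate 3. Of the 2290 strongest regions of replicate 2, 1602 (69.96%) overlapped the 2290 strongest of replicate 3 by at least 1 bp. Random placement gave a mean of 29.3 regions (1.28%) and at most 50 in 1000 placements (one-sided permutation p = 9.99e-04, the smallest that 1000 placements can give). The overlap was 72.6% for the top 500 and 73.7% for the top 1000, and deeper in the lists it was lower, at 59.5% for the top 5000 and 49.3% for the top 10000. Both lists were made against the same control library, and part of the overlap may come from it. Placement was uniform along each chromosome, so it made no allowance for a shared preference for promoters. The IDR list holds the strongest regions of the pooled replicates, so the values in the rest of this paragraph are not independent measures of how well the replicates match. Across 2282 IDR peaks found in both lists, Spearman's rho of the signal values was 0.588; peaks are not independent replicates, so no p is given. Of the IDR peaks, 1867 (81.5%, 95% interval 79.9 to 83.1) overlapped the 2290 strongest regions of replicate 2, and 1982 (86.6%, 85.1 to 87.9) those of replicate 3.

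The strongest peak lay at Xrp1 (FBgn0261113), at 3R:18923986-18924638, in the promoter class, with a signal value of 1970. The next lay at X:2703722-2704055, 39 bp from the TSS of Ugalt, a UDP-galactose transporter gene (1072). The peak nearest to Rh5, which encodes a rhodopsin, was intergenic at 2L:12007119-12007603 (1044). A peak in a 5′ UTR of Tlk, the tousled-like kinase gene, at X:3776420-3776805 had a signal value of 989. The fifth, at 3L:19590452-19590769, lay 88 bp from the TSS of CG14100 (981). Cabut (cbt) was nearest to a peak inside an intron of ush (934), and wnd, a kinase gene of axon injury signalling, had a promoter peak (844). Promoter peaks near px, CG1888, egr, Dp1, ph-p, p53 and Art3 followed, with signal values from 599 to 824. Intronic peaks lay nearest to Lk6, CG11050, ru, CG9663 and REPTOR, and a further 5′ UTR peak lay in crp. Intergenic peaks lay nearest to rdgB, Tom, rpr and CG13323, and the peak nearest to hll lay in a non-coding gene. In all, 11 of the 25 were promoter peaks, 6 intronic, 5 intergenic, 2 in a 5′ UTR and 1 in a non-coding gene.

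p53 itself carried 3 IDR peaks. The gene (FBgn0039044) spans 3R:23049657-23054082. The strongest of its peaks lay at 3R:23053140-23053479, 191 bp from an annotated TSS, with a signal value of 610, and ranked 24 in the IDR list, 25 in replicate 2's list and 23 in replicate 3's list. The others lay at 3R:23053449-23053596 (170) and 3R:23053943-23054338 (107). The eGFP exon is part of this locus, and its position within the gene was not used here.

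The list of p53 radiation-response targets holds genes known to be induced by irradiation through p53. An IDR summit lay within 1 kb of a TSS for 4 of its 10 members, Xrp1, egr, Corp and hid. egr, which encodes a tumour necrosis factor homologue, had a peak at 2R:10078170-10078572 (signal value 675, rank 15, and rank 9 in replicate 2's own list). Corp had a peak at X:8271566-8271792 (313, rank 109), and hid, an activator of cell death, one at 3L:18185596-18185991 (200, rank 282). The rpr gene, another cell death activator, had no summit within 1 kb. Its nearest peak lay 4847 bp from the TSS at 3L:18403116-18403533, and ranked 13 with a signal value of 686 (rank 26 in replicate 2's own list). That peak held the sequence CGACTTGTTCAAACATGTCA (3L:18403257-18403276), which differed from a full p53 site at 2 of 20 positions. The nearest summits to Irbp, Ku80, mre11 and RnrL lay 11883, 19990, 3838 and 23978 bp from a TSS, and that nearest to skl lay 36660 bp away, at the rpr peak. The share of the list (40%) stood against 15.5% of other protein-coding genes, an odds ratio of 3.64 (95% interval 1.03 to 12.9, Fisher's exact p = 0.0553, adjusted p = 0.180), so the list did not pass the threshold. With the upper part of the IDR list by signal value (1145 peaks) the same count of 4 stood against 8.10% of other genes, with an adjusted p of 0.0264. That was the only alternative under which the list passed. The adjusted p was 0.396 under circular shifts, and 0.356 with a single TSS per gene and 0.387 among genes with a pooled region within 1 kb, both chosen after seeing the data.

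The region from hid to skl on 3L (18167745-18439942), which holds hid, grim, rpr and skl, carried 7 IDR peaks. Besides the rpr peak, the strongest were at 3L:18235925-18236339 (342, rank 88) and 3L:18187455-18187850 (277). The first was nearest to CheA75a, 15994 bp from its TSS, and the second lay 2012 bp from a TSS of hid. Weaker peaks of the region were nearest to hid, CG7320 or CG5103. How many peaks a region of this size would hold at random was not asked.

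**Figure D1:**
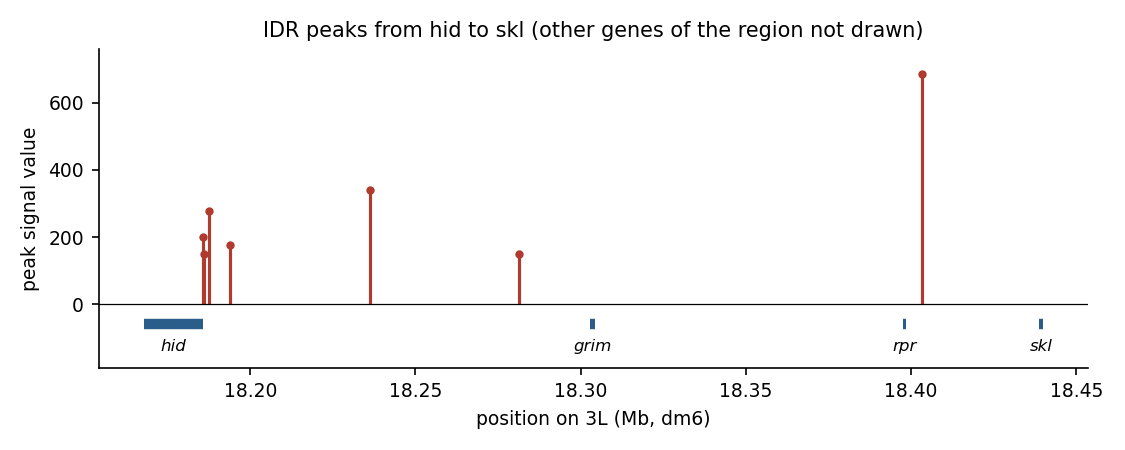
IDR peaks between hid and skl on 3L in dm6. Each line stands at a peak summit and its height is the authors' signal value; blue bars are the genes hid, grim, rpr and skl. The tallest line, at 686, stands 4847 bp from the TSS of rpr.

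The next question was where in the genome the peaks lay. Promoters of protein-coding genes held 1394 of the 2290 IDR summits (60.9%, 95% interval 58.9 to 62.9) and 25.4% of candidate summits, an odds ratio of 4.57 (4.18 to 4.99, Fisher's exact p = 4.0e-252). Coding exons held 12 IDR summits (0.524%) against 17.3% of candidates (exact adjusted p = 4.1e-156), and 1.40% of summits without replicate 3. Introns held 24.5% against 34.4% (exact adjusted p = 4.9e-22), intergenic sequence 10.3% against 17.4% (adjusted p = 4.9e-20), and 3′ UTRs 0.917% against 2.21% (adjusted p = 1.1e-05). The share in 5′ UTRs (0.830% against 1.15%, exact adjusted p = 0.207) and in non-coding genes (2.05% against 2.18%, adjusted p = 0.764) did not pass the threshold. The promoter share was 56.4% in replicate 2's own top regions and 63.1% in replicate 3's.

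**Figure D2:**
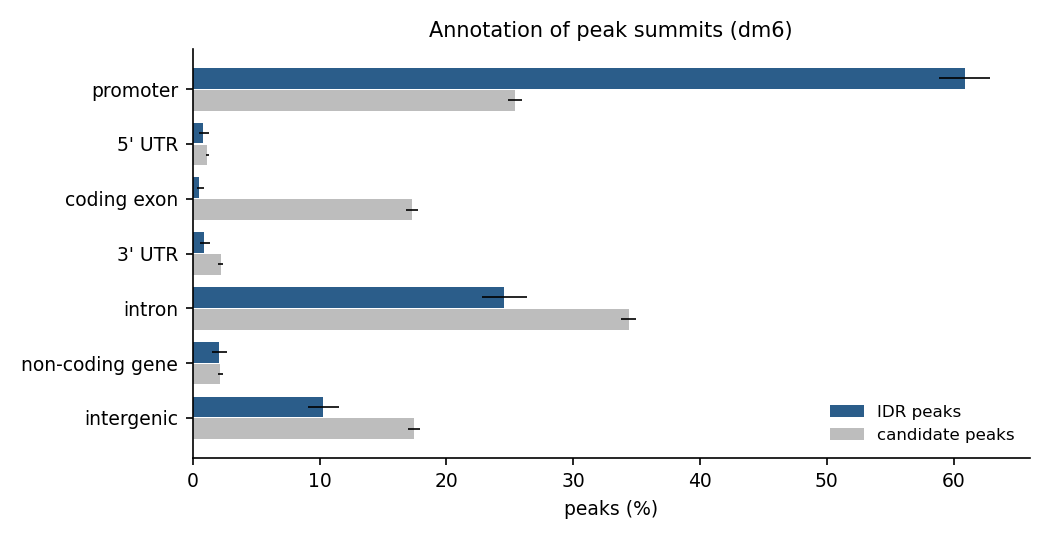
Percent of summits in each annotation class for the 2290 IDR peaks (blue) and the 24040 candidate peaks (grey), with 95% Wilson intervals. Promoters hold 60.9% of IDR summits and 25.4% of candidate summits.

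The X chromosome held 427 IDR peaks (18.6%, 17.1 to 20.3) and 15.6% of candidate peaks, an odds ratio of 1.24 (Fisher's exact adjusted p = 0.00123). Arm 3L held 18.7% against 21.5% (exact adjusted p = 0.00630), and without replicate 3 that difference no longer passed (19.9% against 21.4%, adjusted p = 0.220), nor did it in the upper part of the IDR list by signal value (18.7% against 21.3%, adjusted p = 0.0963). Arms 2L, 2R, 3R and 4 did not pass, with adjusted p from 0.986 to 1. The X makes up 17.6% of the arms by length, and against that share the difference did not pass (exact binomial adjusted p = 0.281). It did not pass among promoter peaks either (17.3% against 17.0%, exact p = 0.813), a split chosen after seeing the data. In the other part of that split, peaks outside promoters, the shares were 20.8% and 15.1% (Fisher's exact p = 1.2e-05).

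The third question was which sequence words the peaks carried. The word of DREF, a factor at promoters of housekeeping and growth genes (TATCGATA), occurred within 100 bp of the summit in 149 IDR peaks (6.51%, 5.57 to 7.59) and in 13 flank windows (0.568%), a 11.5-fold difference (exact binomial adjusted p = 2.1e-29). The word of M1BP, a factor of promoters with paused polymerase (GGTCACAC), occurred in 108 peaks (4.72%) and 16 flanks (0.699%), a 6.75-fold difference (exact adjusted p = 6.4e-18). Without replicate 3 the differences were 6.25-fold for DREF and 4.16-fold for M1BP, and without replicate 2 that for M1BP was 16.9-fold. The GAGA factor word was at 25.5% of summits and 22.3% of flanks (exact adjusted p = 0.0300); without replicate 3 it was at 24.8% and 22.0% (adjusted p = 0.0706). The p53 half-site occurred in 104 peaks (4.54%, 3.76 to 5.47) and 76 flanks (3.32%, 2.66 to 4.13), with an exact p of 0.0439 and an adjusted p of 0.0965 over the 11 words, and did not pass. Against candidate peaks (3.51%) it passed, with an adjusted p of 0.0372. The control word YYYCWWGRRR, the half-site with its ends exchanged, was less frequent at summits (2.45%) than in flanks (4.15%, exact adjusted p = 0.00598), a difference that did not pass without replicate 3 (2.93% and 4.06%, adjusted p = 0.0990) or in the upper part of the IDR list by signal value (3.06% and 3.58%, adjusted p = 1). The words of Zelda, Myc/Max, C/EBP-type factors, the TATA box, Caudal and Jun/Fos did not pass, with adjusted p from 0.200 to 1. In replicate 2's own top regions alone the TATA box passed, at 25.02% of summits and 20.5% of flanks (exact binomial adjusted p = 0.00112).

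**Figure D3:**
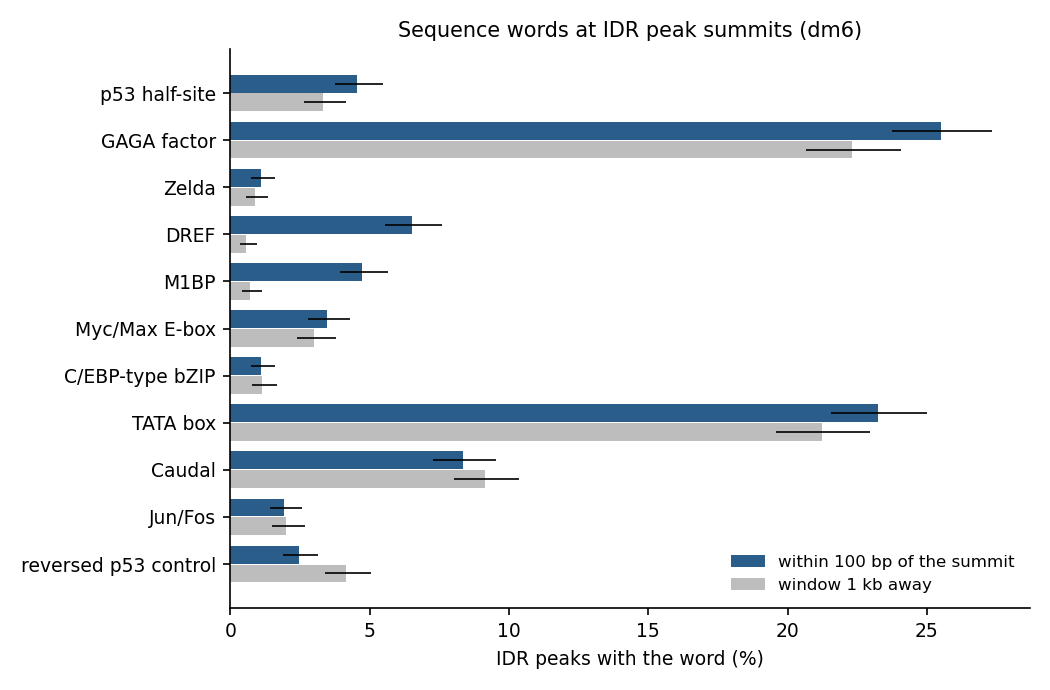
Percent of the 2290 IDR peaks with each word within 100 bp of the summit (blue) and in a window 1 kb away (grey), with 95% Wilson intervals. DREF and M1BP stand apart from their flanks, at 6.51% against 0.568% and 4.72% against 0.699%.

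Whether p53 sites gathered in the strongest peaks was asked by splitting the IDR list by signal value into 5 groups of 458. The half-site occurred in 29 peaks of the strongest group (6.33%, 4.44 to 8.95) and 23 of the weakest (5.02%, 3.37 to 7.42), which did not differ past the threshold (odds ratio 1.28, Fisher's exact p = 0.476). Over all IDR peaks the full site, with at most 3 mismatches, was at 7.21% of summits and 5.85% of flanks, which did not pass (exact binomial adjusted p = 0.157). By group it occurred in 55 (12.01%, 9.34 to 15.3) and 18 (3.93%, 2.50 to 6.13), an odds ratio of 3.34 (Fisher's exact p = 7.5e-06). In replicate 2's own list the odds ratio for the full site was 1.45 (exact p = 0.136), and in replicate 3's own list 2.84 (p = 6.1e-05), a split chosen after seeing the data. Of the 25 strongest peaks, those nearest to Tlk, rdgB, Tom, rpr, crp and p53 held a full site. The best sites at Tlk, rdgB and p53 had 3 mismatches, the most allowed. The site at Tom was CAACAAGTTTCGACTTGTCC (3L:14968340-14968359, 2 mismatches), and that at crp was GGACATGTTTAATCGTGTTT (2L:16287184-16287203, 2 mismatches). No half-site or full site lay within 100 bp of the summit in the peaks at Xrp1, egr, Corp and hid. These are the 4 radiation-response targets with a peak within 1 kb of a TSS, each taken at its strongest.

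**Figure D4:**
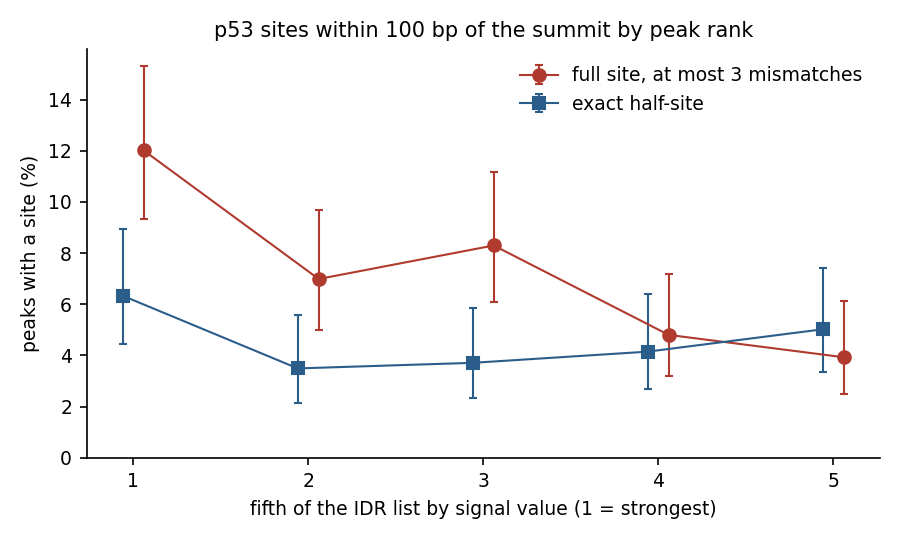
Percent of peaks with a p53 site within 100 bp of the summit in each group of 458 IDR peaks, from the strongest (1) to the weakest (5), with 95% Wilson intervals. Full sites (red) go from 12.01% to 3.93% and exact half-sites (blue) from 6.33% to 5.02%.

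The last question was which kinds of genes had peaks near their TSSs. Of 13968 protein-coding genes, 2164 (15.5%) had an IDR summit within 1 kb of a TSS. Ribosomal protein genes stood far above that level, with peaks at 63 of 92 (68.5%), an odds ratio of 12.2 (7.82 to 18.9, Fisher's exact adjusted p = 3.8e-29). RpL7 (2L:10200913-10201154, signal value 489, rank 42), RpS27 (426, rank 58), RpL23A (413, rank 66) and RpL41 (325) had the strongest of these. The RpS27 peak held a full p53 site, and the other peaks named here held neither a half-site nor a full site. The control library was not used here, so these peaks do not show whether p53 itself sat at ribosomal protein genes. Among genes with a pooled region within 1 kb, a setting chosen after seeing the data, the odds ratio was lower, at 7.60. There 63 of 88 ribosomal protein genes stood against 24.9% of others. The list of replication-dependent histones was drawn up by gene symbol alone, so not every member need be replication-dependent. None of its 112 genes had a peak (exact adjusted p = 5.8e-08), but only 1 of the 112 had any pooled region within 1 kb, and under circular shifts the adjusted p was 0.0866. tRNA genes had peaks at 20 of 290 (6.90%) against 13.4% of other genes (adjusted p = 0.00276), which did not pass without replicate 3 (23 genes, adjusted p = 0.0645) or with the upper part of the IDR list (12 genes, adjusted p = 0.137).

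The other lists did not pass. Cell death genes had peaks at 5 of 18, among them egr, hid, Diap1 (146) and Diap2 (131), the last pair being inhibitors of apoptosis (exact adjusted p = 0.394). DNA damage checkpoint and repair genes had them at 4 of 30, which were p53, Brca2 (108), mus304 (82.1) and tefu, the ATM kinase gene (76.1), with an adjusted p of 1; tefu had none within 1 kb without replicate 3, and without replicate 2 the list had 7 genes with peaks. Cell cycle genes had them at 6 of 25, with Dp (159), dup (129), Cdk4 (114.6) and Rbf (87.1) as the strongest (exact adjusted p = 0.488); Rbf had none without replicate 2. Heat shock genes had them at 5 of 18, among them Hsp83 (238), Hsp27 (152), Hsp26 (126) and Hsp68 (105), with an adjusted p of 0.394. Embryonic patterning genes had them at 6 of 44, among them bcd (153), rho (153), wg (97.6) and oc (94.97), with an adjusted p of 1; without replicate 3 the list had 3 genes with peaks, and oc had none. Neuronal and glial markers had them at 5 of 30, with moody (310), elav (168), Appl (139) and futsch (111) as the strongest (exact adjusted p = 1). Muscle markers had them at 5 of 22, among them Msp300 (233), sls (94.8), rols (83.2) and Mef2 (82.7), with an adjusted p of 0.603. Germline and piRNA genes had them at 5 of 26, among them bgcn (194), zpg (153), vas (146) and tud (101), with an adjusted p of 0.847. Hemocyte, fat body and gut markers had them at 3 of 22, which were ush (189), fkh (157) and Hml (102), with an adjusted p of 1. In this paragraph the number after a gene is the signal value of its strongest peak within 1 kb of a TSS.

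**Figure D5:**
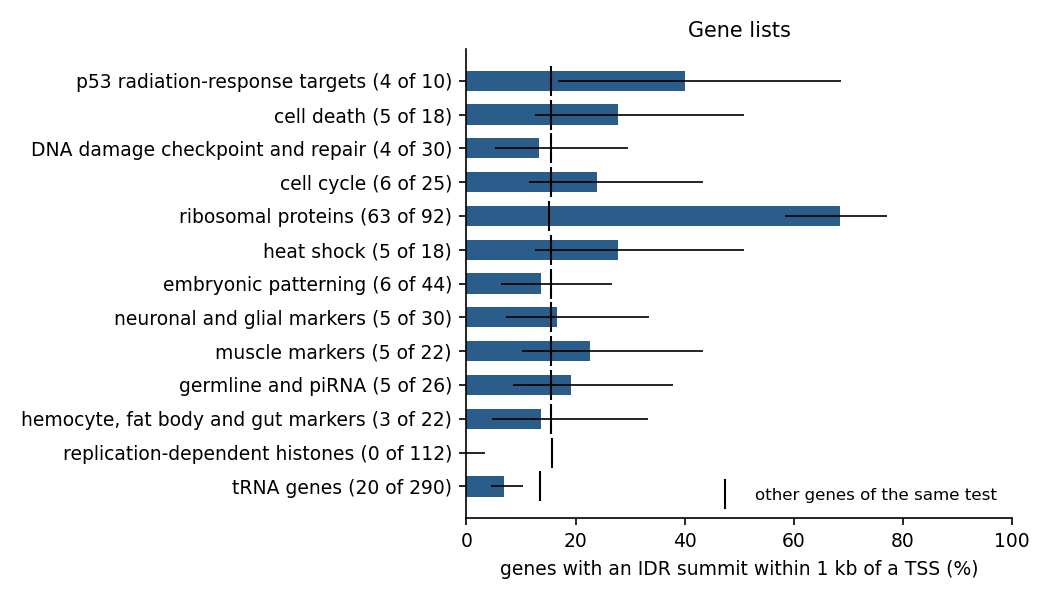
Percent of the genes of each list with an IDR summit within 1 kb of a TSS (bars, with 95% Wilson intervals) and the percent among the other genes of the same test (vertical marks). Ribosomal protein genes stand at 68.5% and the other protein-coding genes at 15.1%.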

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

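The dm3 lists name heterochromatic and unplaced sequences apart from the chromosome arms, and the dm6 lists name none. With no conversion between builds, it was not asked if the same DNA lies on the dm6 arms. In the dm3 pooled list, 4 regions on such sequences had a deposited q of 0.05 or less, of 4464 at that q in the list. Replicate 3's list held 4 as well. Counts above 3 were flagged, a rule that does not test for an excess. In the pooled list they lay 1 each on 3LHet, 3RHet, U and Uextra, with signal values from 53.1 to 71.3, and none was in the IDR list. Replicate 2's list held 2. No explanation was tested.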

How the results depend on the processing

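The settings that took a single TSS per gene, only genes with a pooled region within 1 kb, promoter peaks or other peaks alone, the full p53 site by rank in each replicate's own list, or the half-site with the core CATG (1 of 6 forms looked at) were chosen after seeing the data. The pooled list's strongest 2290 regions are the IDR list itself, so that setting tests nothing, and its values are left out of the counts here. Of 216 values with a p under the other alternatives, 170 kept their direction and their side of the threshold, 12 lost a call, 4 gained 1 and 30 changed direction. Of 18 values with no p, 17 stayed close to the main value and 1 count moved by more than 1.5-fold. For named peaks and genes only the presence of a peak was followed: of 185 values, 170 kept one in the list used and 15 did not, whatever its rank. Promoter share, replicate overlap, the DREF and M1BP words and ribosomal protein genes kept their calls under every alternative run, and the rank correlation stayed between 0.579 and 0.588. The upper part of the IDR list holds 1145 peaks by construction. The X share of 18.6% did not pass against chromosome length, nor did 17.3% among promoter peaks; the p53 half-site share of 4.54% passed against candidates; and the odds ratio by rank rose to 3.34 with the full site. Why the half-site passed against candidates was not tested. The changes of direction were among results that passed neither before nor after. In the upper part of the IDR list they were 5′ UTR (1.14%), non-coding genes (2.18%), 2R (18.1%), Myc/Max (3.41%), Caudal (8.82%), Jun/Fos (2.36%), muscle (1 gene) and hemocyte, fat body and gut markers (2). Random placements turned 5′ UTR (0.830%), and chromosome length turned 3R (24.0%). Leaving out a replicate gave 18.7 to 19.0% for 2L, 17.5 to 20.1% for 2R, 0.742% for 4, 0.917 to 0.961% for Zelda, 2.93 to 3.67% for Myc/Max, 1.00% for C/EBP-type factors, 4 to 7 DNA damage genes and 4 to 5 neuronal genes. A 500 bp TSS window turned DNA damage (4 genes) and neuronal genes (3), and a single TSS turned muscle (2). Gene bodies plus 1 kb turned DNA damage (6), patterning (10), germline (5) and hemocyte markers (5). Genes with a pooled region turned cell cycle (6), germline (5) and hemocyte markers (3). No paired analysis was possible because there is 1 group. Read depth per peak was not used here, so it sets no limit that can be stated.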

Other observations

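All 8-letter words within 100 bp of the summit were compared with 1 flank window per peak, a search chosen after seeing the data. Before it, words of 6 and 8 letters had been looked at in 4 parts of the list, the top 100, the top 458, promoter peaks and other peaks, with flanks at 2 distances, and the adjusted p values here do not count those looks. Among 896 IDR peaks outside promoters, 20 of 32533 words passed an adjusted p of 0.05. AGATGGCG, which holds core letters of the known site of the insulator protein CTCF, occurred at 37 summits (4.13%) and 1 flank (0.112%, exact binomial adjusted p = 4.6e-06). CACTGAGA occurred at 53 summits (5.92%) and 6 flanks (0.670%, exact adjusted p = 4.6e-06). Among 1394 promoter peaks, 362 of 32854 words passed, led by ATCGATAG at 152 summits (10.9%) and 7 flanks (0.502%, exact adjusted p = 7.1e-33), which overlaps the DREF word. Among the 100 strongest peaks no word passed; the lowest p was shared by AAACATGT and CAAATAAA, each at 8 summits and 0 flanks (exact p = 0.00781, adjusted p = 1). Overlapping words share sites, so these counts are not independent.

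In what follows, what the X share against chromosome length would show under each explanation was written after that result was seen. The splits of the X share by promoter and of the full site by replicate were chosen after seeing the data. No biological explanation was tested for any pattern, because the series has 1 group.

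The DREF or M1BP word occurred at 230 of 1394 IDR promoter summits (16.5%) and at 14 of 896 others (1.56%). IDR promoter summits carried either word more often than candidate promoter summits (9.69%, odds ratio 1.84, 95% interval 1.56 to 2.17). The promoter class alone therefore does not account for the IDR share. Distance to the TSS was not matched in that comparison. A narrower TSS window held 52.6% of IDR and 17.9% of candidate summits, against 60.9% and 25.4% in the window used here. IDR promoter summits thus lay nearer to a TSS, and position within the promoter is not ruled out as the cause. A single replicate as the source is argued against, because the smaller of the replicates' folds over flanks was 5.03 (exact binomial p = 3.8e-27). A candidate explanation is precipitation of active promoter chromatin that does not need a p53 site. Full p53 sites were at 5.33% of peaks with either word and 7.43% of others (odds ratio 0.701, 0.392 to 1.26). In the flanks of the peaks with either word they were at 7.79% (exact binomial p = 0.377). These values cannot tell that explanation from binding of p53 through other proteins, and the control library was not used here.

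Full p53 sites were more frequent in the strongest group of 458 IDR peaks than in the weakest. A change in promoter share along the list does not account for it, since the Mantel-Haenszel odds ratio with promoter and other peaks kept apart was 3.29 (1.90 to 5.71). The shares were 9.19% and 3.47% in promoters and 16.1% and 4.71% outside them. Windows 1 kb away gave an odds ratio of 0.9502 (0.508 to 1.78), so base composition at that distance does not account for it either. Composition at the summits themselves was not compared, so it is not ruled out. In replicate 2's own list the odds ratio was 1.45 (Fisher's exact p = 0.136), with full sites at 10.7% of the strongest group and 7.64% of the weakest. In replicate 3's own list it was 2.84, with 12.01% and 4.59%. The replicates' odds ratios were not compared by a test, so whether the pattern depends on replicate 3 is open. The pattern stays a hypothesis.

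The X held a larger share of IDR than of candidate peaks. With promoter and other peaks kept apart the odds ratio was 1.19 (1.07 to 1.34), so promoter share alone does not account for it. Outside promoters the X held 20.8% of IDR and 15.1% of candidate peaks, and the odds ratio there was 1.44-fold that at promoters (95% interval 1.15 to 1.81). The excess may come from fewer candidate peaks on the X, whose share was 15.6% (upper bound 16.1%) against 17.6% of the length, while the lower bound for IDR peaks, 17.1%, did not exceed the length share. That comparison took all IDR peaks together. It was not made for peaks outside promoters, where the excess lay, so it does not settle the cause there.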
